A study of Arabidopsis thaliana with 12 samples.

How the data were processed

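Messenger RNA was sequenced from 12 whole-seedling samples of Arabidopsis thaliana, ecotype Col-0, extracted with a plant RNA kit and made into stranded mRNA libraries, per the labels' protocols. The samples form 4 groups of 3 (pfd4 and WT at 14 days, 6x_pfd and WT at 7 days), taken from the titles and the genotype and growth labels. The titles of the 14-day samples carry the word mock, and the labels describe no treatment. Each mutant was compared with the WT of its own experiment, and the comparisons share no libraries.

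The authors used cutadapt, HISAT2, HTSeq and DESeq2 with the genome build TAIR10, per the submitters' processing notes, which give no versions, roles or order. Whether HTSeq counted by strand, and how reads shared by genes were counted, is not given in the sources used here. Per the file headers, the authors' deposited tables hold for each gene a mean normalized count, a log2 fold change between genotypes with its standard error (SE), also on the log2 scale, a Wald test score, a p-value and an adjusted p-value. The deposited Wald score equalled the log2 fold change divided by its SE within 6.758e-11 in the pfd4 table, and the deposited adjusted p-values equalled a Benjamini-Hochberg adjustment of all p-values in each table within 2.666e-15. The names of the deposited tables say that genes were filtered on a minimum RPKM by the authors, in a way not given in the sources used here. A separate deposited list per comparison repeats the log2 fold change and adjusted p-value of the genes past both an adjusted p of 0.05 and an absolute log2 fold change of 1. Fold changes are mutant over WT, a direction checked on PFD4, which is lower in pfd4.

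The tables give no values per library, so library depth, the spread between replicates and leave-one-out values were not analysed here, and no count model was fitted. The planned count model, the planned interaction model and the tests with an estimated correlation between genes or with fry could therefore not be run. The fallback set before the data were examined was used for each mutant: the values of the authors' deposited tables with no new test, called at an adjusted p below 0.05. The SE is the only record of precision. The p-values weigh each log2 fold change against that SE, which rests on the 3 samples of each group that the series' design text calls biological. The difference between the mutant effects replaced the planned interaction. It was a two-sided Wald test of the difference of log2 fold changes over the root of the summed squared SEs, with Benjamini-Hochberg adjustment, chosen after it was seen that no values per library were in the tables. Genotype, age and light regime are confounded in it.

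Overlaps between the mutants used the 18035 genes tested in both tables, two-sided Fisher's exact tests and the number given by independent lists. Before the data were examined, 29 gene lists with 455 genes were fixed, together with chloroplast-encoded and mitochondria-encoded genes and cytosolic ribosomal proteins, 32 lists in all. The ribosomal list, defined by product names, matched 8 genes of the reference, of which 5 were measured, so a broader list by annotated location was added after the data were seen. Lists were tested with cameraPR of limma on the Wald score, with a preset correlation of 0.01, and of 0.05 and 0.1 and on ranks as added alternatives, and adjusted p-values of list tests are from limma with Benjamini-Hochberg adjustment over 31 lists per comparison. Process terms were taken from the notes of the TAIR10.1 annotation, for terms of 10 to 500 genes, and tested with Fisher's exact test. IDs of 18288 of the 18366 genes of the pfd4 table and 19310 of the 19397 genes of the 6x_pfd table matched that annotation, which was used for names, products and neighbouring genes, and no coordinates are given because the named assemblies differ.

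The genes named in the text follow a rule fixed before the data were examined, apart from the exceptions given here. It takes the 6 prefoldin genes, the 8 largest changes in each direction past the threshold with a mean of at least 1 CPM, up to 4 members with the smallest p of each list that moved, and the 10 genes past the threshold in both mutants with the smallest larger p. Its condition that the 3 mutant values lie outside the range of the 3 WT values could not be applied, and the minimum was applied to CPM values computed from the mean normalized counts. List members named because they moved against their list or did not pass (MYB111, MYBL2, JAZ6 in 6x_pfd, HSFA7A, LHCB4.3, FRO2, IRT1, FER4, TUB1), genes named in the difference and the paralog TUB2 were chosen after their values were seen. So were BCS1, CRF6, NAC13, CYP81D8, AT5G14730, ERF6, ERF104, WRKY40, WRKY33, LOX4 and HEI10, named in the additional observations. Not every gene that the rule takes is named in the text.

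Alternatives were an FDR of 0.01 and an absolute log2 fold change of at least 1, set before the data were examined, and 4 added after they were seen. These were a filter at 5 CPM of the mean normalized count, centring of fold changes on equal library totals rebuilt from the tables, Wald scores divided by their robust SD (an empirical null), and a test against a change of 25% (1.25-fold). The robust SD of the Wald score was 1.38 in the pfd4 table and 2.34 in the 6x_pfd table. It was taken over all tested genes, of which 7.75% and 33.6% were called, so real changes widen it too. Counts under the empirical null therefore do not measure how many deposited calls are false. Centring shifted the fold changes by the log2 ratio of totals, -0.00779 in pfd4 and -0.0783 in 6x_pfd. The calculations were tested on simulated data drawn from the tables' SEs with 200 changed genes per comparison. Of genes changed by 0.5, 1 and 2 on the log2 scale, 53.6%, 93.2% and 98.6% were called among 18363 simulated genes for pfd4, and 60.8%, 90.7% and 97.0% among 19380 for 6x_pfd. That simulation takes the SEs as correct. It holds fewer changed genes than the 1423 and 6519 called in the authors' deposited tables, which makes the adjustment stricter. Its shares are therefore not those of the deposited calls. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.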

Results

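Stranded mRNA libraries were made from whole Arabidopsis thaliana seedlings of the Col-0 ecotype, in 4 groups of 3 samples each that the labels call biological samples. In the first experiment, pfd4 and wild-type (WT) seedlings were grown in vitro for 14 days under the label LD, the usual name of long days, and collected at ZT1. In the second, 6x_pfd and WT seedlings were grown for 7 days under the label LL, the usual name of continuous light. Prefoldin is a chaperone complex of 6 subunits, PFD1 to PFD6, that hands unfolded tubulin and actin to the cytosolic chaperonin CCT. The comparisons ask which transcripts differ between each prefoldin mutant and the WT of its own experiment. Values come from the authors' deposited tables, where ± is the standard error (SE) of the log2 fold change, mutant over WT, from 3 libraries per group. Depth per library and values per replicate were not analysed here, so the spread between replicates enters only through that SE. The mean normalized counts of the authors' deposited tables summed to 29221246 for pfd4 and 32374115 for 6x_pfd, and the median SE per gene was 0.126 and 0.121.

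PFD4 was the prefoldin gene that changed in pfd4, with a log2 fold change of -1.99 ± 0.17 (adjusted p = 1.0e-29) in the authors' deposited table. PFD1, PFD2, PFD3, PFD5 and PFD6 lay between 0.00 and 0.11 there and did not pass the threshold. In 6x_pfd, 5 of the 6 genes fell. PFD1 was at -7.03 ± 0.42, PFD4 at -3.78 ± 0.19, PFD3 at -3.36 ± 0.12 and PFD2 at -2.85 ± 0.13 in the authors' deposited table. PFD5 was at -1.15 ± 0.13 (adjusted p = 2.8e-18) and PFD6 at -0.16 ± 0.10 (adjusted p = 0.22) in the authors' deposited table. Adjusted over the list alone, the counts were again 1 of 6 in pfd4 and 5 of 6 in 6x_pfd. A transcript level does not show whether an allele leaves a working protein.

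**Figure D1:**
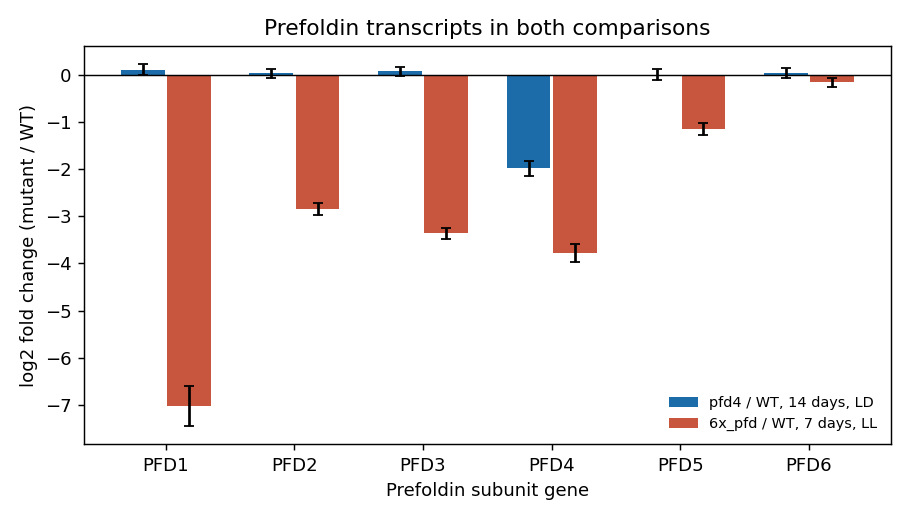
Log2 fold change (mutant over WT) of the 6 prefoldin subunit genes in pfd4 at 14 days (blue) and 6x_pfd at 7 days (red), with bars for the estimate and error bars for the SE in the authors' deposited tables. In pfd4 the bar away from 0 is PFD4 at -1.99, while in 6x_pfd PFD1 to PFD5 lie between -7.03 and -1.15 and PFD6 is at -0.16.

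In pfd4 seedlings at 14 days, jasmonate and flavonoid genes were higher than in WT, and heat shock, tubulin and iron homeostasis genes, and those of the cell cycle and DNA replication, were lower. The jasmonate enzyme gene AOC2 rose by 2.87 ± 0.24 and the anthocyanin enzyme gene DFR by 1.79 ± 0.22 on the log2 scale in the authors' deposited table. The heat shock factor gene HSFA2 (-1.45 ± 0.20) and the disaggregase gene HSP101 (-1.29 ± 0.16) fell in the authors' deposited table. In all, 1423 of 18366 genes passed a false discovery rate (FDR) of 0.05 in the authors' deposited table, 724 higher and 699 lower, and their median absolute log2 fold change was 0.487. Of these, 198 also changed by more than 1 on the log2 scale, 147 higher and 51 lower, and they are the 198 genes of the authors' deposited list, whose title states 199. With the empirical null 347 genes passed in pfd4, and 165 in the test against a 25% change.

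The largest increases in pfd4 in the authors' deposited table were in MBP1, a myrosinase-binding protein (4.21 ± 0.21), AT2G16367 (3.73 ± 0.47), NUDT24, a nudix hydrolase (2.96 ± 0.40), and AT1G52000, a mannose-binding lectin (2.95 ± 0.15). AOC2, the Kunitz inhibitor gene AT1G73325 (2.74 ± 0.33), the myo-inositol oxygenase gene MIOX4 (2.63 ± 0.38) and AT5G51190 (2.58 ± 0.26) followed in the authors' deposited table. AT3G01345, an uncharacterized protein gene, was at -8.01 ± 0.25, AT5G15360 at -5.40 ± 0.43 and MRD1 at -5.02 ± 0.30 in the authors' deposited table. Smaller decreases were those of AT1G58320 (-2.33 ± 0.58), PER4 (-2.05 ± 0.40), PFD4, WSD1 (-1.88 ± 0.30) and DIN2 (-1.87 ± 0.38) in the authors' deposited table.

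Of the cytoskeleton and chaperone lists in pfd4, 8 of 15 tubulin genes fell (12 adjusted over the list alone) and none rose in the authors' deposited table, with a median of -0.33 and a list test at adjusted p = 8.93e-11. TUB9 (-0.54 ± 0.08), TUB7 (-0.44 ± 0.08) and TUB4 (-0.43 ± 0.08) had the smallest p in the authors' deposited table. Of 9 genes for subunits of CCT, 3 fell (7 adjusted over the list alone), CCT8 (-0.29 ± 0.07), CCT4 (-0.25 ± 0.07) and CCT6B (-0.27 ± 0.08) in the authors' deposited table, with adjusted p = 0.000103 for the list. Of 26 heat shock genes, 15 fell (16 adjusted over the list alone), the median was -0.52 and the list test gave adjusted p = 1.31e-18. FES1A (-1.27 ± 0.16) and MBF1C (-0.90 ± 0.12) were among them in the authors' deposited table. All 6 genes for cytosolic HSP90 and HSC70, the constitutive chaperones, fell (6 adjusted over the list alone) with a median of -0.63 and adjusted p = 1.41e-11. HSC70-3 was at -1.25 ± 0.15 and HSP90.3 at -0.80 ± 0.14 in the authors' deposited table. Among 6 actin genes, ACT11 fell (-0.44 ± 0.15) in the authors' deposited table, and the list test did not pass (adjusted p = 0.189).

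Of 16 jasmonate genes, 13 rose in pfd4 (13 adjusted over the list alone) and none fell, with a median of 0.69 and adjusted p = 1.56e-26. AOC1 (1.67 ± 0.14) and the repressor genes JAZ5 (1.72 ± 0.24) and JAZ6 (0.92 ± 0.14) were among them in the authors' deposited table. Of 16 flavonoid and anthocyanin genes, 9 rose (10 adjusted over the list alone) and 1 fell, the regulator gene MYB111 (-0.88 ± 0.21), in the authors' deposited table. TT19 (1.52 ± 0.22), LDOX (1.497 ± 0.227) and UF3GT (2.16 ± 0.37) rose in the authors' deposited table, and the list test gave adjusted p = 5.10e-11. Light-harvesting genes rose by a small amount: 11 of the 22 genes for light-harvesting proteins and the Rubisco small subunit passed (14 adjusted over the list alone), with a median of 0.23 and adjusted p = 1.21e-09. LHCB1.2 was at 0.38 ± 0.08 and LHCA4 at 0.32 ± 0.07 in the authors' deposited table. Of 13 flowering time genes, 2 rose (4 adjusted over the list alone), the floral repressor genes FLC (1.099 ± 0.211) and MAF5 (1.89 ± 0.41), in the authors' deposited table, with adjusted p = 0.00246 for the list, or 0.265 under the abundance filter.

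Of 15 iron homeostasis genes, 6 fell in pfd4 (9 adjusted over the list alone) and none rose, with adjusted p = 3.12e-09. They included PYE, a regulator of the iron-deficiency response (-0.88 ± 0.14), and the signalling peptide genes IMA1 (-1.34 ± 0.22) and IMA3 (-0.64 ± 0.11) in the authors' deposited table. Root markers had a median of -0.63 and adjusted p = 1.53e-05, with 2 of 12 genes lower (9 adjusted over the list alone), among them the Casparian strip gene CASP2 (-0.66 ± 0.16) in the authors' deposited table. Of 20 cell cycle and DNA replication genes, 7 fell (8 adjusted over the list alone), such as the replication helicase genes MCM7 (-0.51 ± 0.10) and MCM2 (-0.56 ± 0.11) in the authors' deposited table, with adjusted p = 0.000143. Cell wall loosening genes were lower in 3 of 17 cases (5 lower and 1 higher adjusted over the list alone), led by the expansin genes EXPA5 (-0.59 ± 0.10) and EXPA1 (-0.61 ± 0.14) in the authors' deposited table. Of 19 clock genes, LNK1 (-0.33 ± 0.09) and PRR9 (-0.50 ± 0.13) fell (7 adjusted over the list alone) in the authors' deposited table. The cell wall and clock lists passed at the preset correlation of 0.01 (adjusted p = 0.023 and 0.0372), and at a preset correlation of 0.05 adjusted p rose to 0.0923 and 0.125. On ranks it was 0.120 and 0.110, and for the clock 0.0945 under the abundance filter.

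Other lists did not pass in pfd4. In the authors' deposited table, higher and lower counts were 1 and 2 of 11 cold response genes (2 and 3 adjusted over the list alone), 1 and 1 of 15 abscisic acid and drought genes, 1 and 1 of 11 salicylic acid and immunity genes, and 2 and 1 of 20 glucosinolate genes, the last 3 with the same counts adjusted over the list alone. One direction each was seen for the endoplasmic reticulum (ER) unfolded protein response (1 of 11 lower, and 1 adjusted over the list alone), gibberellin genes (1 of 15 higher, with 1 more lower adjusted over the list alone) and oxidative stress genes (1 of 13 higher, and 1 adjusted over the list alone). No gene passed, and none did adjusted over the list alone, among 14 auxin response, 6 seed storage, 5 DNA damage, 6 phosphate starvation, 18 SR splicing factor, 11 LSM, 66 chloroplast-encoded, 12 mitochondria-encoded and 5 cytosolic ribosomal protein genes in the authors' deposited table. Floral organ markers were not measured in pfd4. Signs of median, mean and test differed for the prefoldin, cold, salicylic acid and glucosinolate lists, none of which passed. The list tests used preset correlations between genes, since an estimated correlation needs values per library, and 13 of 31 lists passed at 0.01 and 11 at both 0.05 and 0.1.

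In 6x_pfd seedlings at 7 days, abscisic acid, cold, seed storage and flavonoid genes were higher than in WT. Light-harvesting, tubulin, auxin response and cell wall loosening genes were lower. The drought-induced gene RD20 rose by 2.65 ± 0.12 and the anthocyanin regulator gene TT8 by 3.37 ± 0.26 on the log2 scale in the authors' deposited table. LHCB1.4, a light-harvesting chlorophyll-binding protein, was at -2.01 ± 0.11 and TUB8 at -0.97 ± 0.08 in the authors' deposited table. At an FDR of 0.05, 6519 of 19397 genes passed in the authors' deposited table, 3270 higher and 3249 lower, with a median absolute log2 fold change of 0.507. After centring the fold changes on equal library totals, 7040 genes passed and 66.1% of them were higher, against 50.2% as deposited. Centring removed the log2 ratio of totals, -0.0783, from every fold change, whose median was 0.00135 as deposited. The larger share of higher genes follows from that upward shift. With the empirical null 923 genes passed, and 1779 in the test against a 25% change. The empirical null takes its scale from all tested genes, of which 33.6% were called here. It thus divides out real changes as well, and the lower count does not show that the deposited calls are false. The 1186 genes that also changed by more than 1 on the log2 scale, 734 higher and 452 lower, are those of the authors' deposited list.

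The largest increases in 6x_pfd in the authors' deposited table were in AT1G30170 (10.01 ± 1.21), AT2G18190 (9.13 ± 1.07), the thionin gene THI2.1 (8.365 ± 1.2005) and the efflux transporter gene AT2G04070 (8.19 ± 0.70). AT4G05380 (7.72 ± 0.76), AT5G53230 (7.39 ± 0.86), the seed storage gene SESA2 (6.86 ± 1.17) and the transporter gene AT2G04050 (6.77 ± 0.54) came next in the authors' deposited table. Fold changes of this size need a very low level in one group, so their exact size is uncertain. Outside the prefoldin genes, the largest decreases in the authors' deposited table were in AT2G05950 (-3.61 ± 0.31), AT5G43520 (-3.41 ± 0.43), the defensin-like gene AT3G59930 (-2.99 ± 0.22) and the thionin gene AT1G66100 (-2.85 ± 0.14).

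All 18 abscisic acid and drought genes rose in 6x_pfd (18 adjusted over the list alone), with a median of 2.15 and adjusted p = 1.38e-47. Examples were P5CS1, for proline synthesis (2.43 ± 0.14), the phosphatase gene HAI1 (3.38 ± 0.21) and the homeobox gene ATHB7 (2.204 ± 0.126) in the authors' deposited table. Of 13 cold response genes, 11 rose (11 adjusted over the list alone), among them KIN1 (2.98 ± 0.12), RD29A (2.57 ± 0.15) and LTI30 (1.79 ± 0.10) in the authors' deposited table, with adjusted p = 2.36e-25 for the list. Of 15 seed storage and late embryogenesis genes listed, 8 were in the authors' deposited table, which the authors filtered on a minimum RPKM, and these rose (8 adjusted over the list alone), with a median of 3.79 and adjusted p = 1.01e-08. Genes nearly silent in WT may have met that filter only because they were high in 6x_pfd. For such members the filter fixes the direction, so the count and the list test give no independent support. EM6 was at 3.40 ± 0.24 and EM1 at 4.85 ± 0.70 in the authors' deposited table. Of 18 flavonoid and anthocyanin genes, 16 rose (17 adjusted over the list alone) and the repressor gene MYBL2 fell (-2.07 ± 0.22) in the authors' deposited table. CHS, the entry enzyme of the pathway, was at 2.06 ± 0.14 and F3H at 1.94 ± 0.13 in the authors' deposited table, with adjusted p = 4.72e-22 for the list.

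Of 19 jasmonate genes, 11 rose in 6x_pfd (12 adjusted over the list alone) and JAZ6 fell (-0.53 ± 0.16) in the authors' deposited table, with adjusted p = 1.64e-05. LOX2 (1.93 ± 0.13), AOC2 (1.46 ± 0.13) and AOS (0.66 ± 0.10), which encode biosynthetic enzymes, rose in the authors' deposited table. Of 14 salicylic acid and immunity genes, 7 rose (7 adjusted over the list alone), such as PBS3 (3.03 ± 0.30) and PR1 (3.84 ± 0.66) in the authors' deposited table. That list passed at adjusted p = 0.00295 and was at adjusted p = 0.0509 with a preset correlation of 0.1 and 0.191 under the abundance filter. Of 6 DNA damage response genes, 4 rose (4 adjusted over the list alone), with GMI1 at 2.79 ± 0.16, SMR5 at 1.56 ± 0.30 and PARP2 at 0.89 ± 0.13 in the authors' deposited table and adjusted p = 0.000166 for the list. Of 13 oxidative stress and detoxification genes, 5 rose and 2 fell (5 and 3 adjusted over the list alone). UPOX (2.69 ± 0.25), UGT74E2 (2.47 ± 0.18), GSTF6 (1.98 ± 0.21) and the alternative oxidase gene AOX1A (0.80 ± 0.08) rose in the authors' deposited table, with adjusted p = 0.0115 for the list and 0.0995 with a preset correlation of 0.1. A rank-based form of that test did not pass (adjusted p = 0.471).

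Of 22 heat shock genes measured in 6x_pfd, 14 rose (16 adjusted over the list alone) and the heat shock factor gene HSFA7A fell (-1.17 ± 0.25) in the authors' deposited table. HSP22.0 (5.34 ± 0.57), HSP17.4 (3.02 ± 0.36), HSP70-4 (1.53 ± 0.15) and HSP23.5 (1.21 ± 0.17) rose in the authors' deposited table, and the list had adjusted p = 7.54e-06. Of the 6 HSP90 and HSC70 genes, 5 rose (5 adjusted over the list alone), HSC70-2 by 0.45 ± 0.12 in the authors' deposited table, and the list test did not pass (adjusted p = 0.0904) unless it was run on ranks (adjusted p = 0.0127). In the ER unfolded protein response, 4 of 12 genes rose (5 adjusted over the list alone), including the transcription factor genes NAC103 (1.88 ± 0.25) and bZIP60 (0.45 ± 0.14) in the authors' deposited table, with adjusted p = 0.182 for the list. No gene of the 9 for CCT subunits passed, and none did adjusted over the list alone, with a median of 0.13 in the authors' deposited table and adjusted p = 0.205, or 0.0152 on ranks. Tubulin genes fell in 14 of 15 cases (14 adjusted over the list alone), with a median of -0.51 and adjusted p = 3.68e-13. TUB5 was at -0.81 ± 0.07, TUA3 at -0.60 ± 0.06 and TUB1, which did not pass, at 0.10 ± 0.10 in the authors' deposited table. Of 6 actin genes, ACT11 (-0.36 ± 0.08) and ACT3 (-0.31 ± 0.09) fell (3 adjusted over the list alone) in the authors' deposited table, with adjusted p = 0.185 for the list.

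Of the 22 genes for light-harvesting proteins and the Rubisco small subunit, 17 fell in 6x_pfd (17 adjusted over the list alone) and LHCB4.3 rose (0.95 ± 0.18) in the authors' deposited table, with adjusted p = 1.10e-27. LHCA3 was at -1.26 ± 0.10 and LHCB5 at -1.13 ± 0.08, and the 4 Rubisco small subunit genes lay between -0.22 and 0.16 and did not pass in the authors' deposited table. Chloroplast-encoded genes went the other way: 49 of 76 rose (56 adjusted over the list alone), with a median of 1.27 in the authors' deposited table and adjusted p = 1.76e-07. These transcripts mostly lack stable poly(A) tails, so an mRNA library captures them unevenly. No gene of 11 mitochondria-encoded genes passed, with none adjusted over the list alone. Of 17 auxin response genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone), with the transporter gene PIN3 at -0.93 ± 0.07 and IAA7 at -0.85 ± 0.07 in the authors' deposited table and adjusted p = 2.09e-07 for the list. Of 18 cell wall loosening genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone), with EXPA8 at -1.85 ± 0.14 and EXPA1 at -1.45 ± 0.10 in the authors' deposited table and adjusted p = 6.45e-06 for the list. Of 19 glucosinolate genes, 12 fell and 1 rose (13 and 2 adjusted over the list alone), with MYB29 at -1.14 ± 0.20 and MAM1 at -0.94 ± 0.14 in the authors' deposited table and adjusted p = 0.000821 for the list.

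Of 15 iron homeostasis genes, 10 rose and 3 fell in 6x_pfd (10 and 3 adjusted over the list alone), with adjusted p = 8.43e-07. The transcription factor genes bHLH100 (3.13 ± 0.19), bHLH38 (2.90 ± 0.22) and bHLH39 (2.31 ± 0.18) and the peptide gene IMA1 (1.58 ± 0.13) rose in the authors' deposited table. The root iron uptake genes FRO2 (-1.37 ± 0.23) and IRT1 (-1.26 ± 0.25) and the ferritin gene FER4 (-0.87 ± 0.15) fell in the authors' deposited table. Of 14 root and root hair markers, 9 rose (9 adjusted over the list alone), with the root hair genes PRP3 at 0.96 ± 0.16 and RSL4 at 0.90 ± 0.22 in the authors' deposited table. Of 23 clock genes, 10 fell and 5 rose (10 and 5 adjusted over the list alone), with LNK2 at -1.77 ± 0.13, PRR7 at -1.29 ± 0.18 and CCA1 at -0.95 ± 0.10 in the authors' deposited table. Of 20 cell cycle and DNA replication genes, 9 fell (9 adjusted over the list alone), with KNOLLE at -0.66 ± 0.09 and CDKB2;1 at -0.64 ± 0.11 in the authors' deposited table. The genes that fell differed in part from those in pfd4. MCM7 (-0.18 ± 0.13) and MCM2 (-0.03 ± 0.12) did not pass in 6x_pfd in the authors' deposited table. KNOLLE (0.01 ± 0.10) and CDKB2;1 (-0.11 ± 0.11) did not pass in pfd4 in the authors' deposited table. The root, clock and cell cycle lists passed at adjusted p = 0.0138, 0.00659 and 0.00659, and with a preset correlation of 0.1 adjusted p was 0.109, 0.115 and 0.109. On ranks the clock list had adjusted p = 0.104.

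Flowering time genes went both ways in 6x_pfd, with 2 of 13 lower and 2 higher (2 and 2 adjusted over the list alone). SVP was at -0.67 ± 0.08, SPL3 at -1.70 ± 0.24, SMZ at 0.43 ± 0.11 and FLC at 0.77 ± 0.20 in the authors' deposited table, with adjusted p = 0.639 for the list. Of 17 gibberellin genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone), GASA6 being at -1.05 ± 0.16 and GID1B at 0.44 ± 0.11 in the authors' deposited table, with adjusted p = 0.775 for the list. Of 10 phosphate starvation genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone), PAP17 being at 0.61 ± 0.09 and IPS1 at -1.44 ± 0.22 in the authors' deposited table, with adjusted p = 0.521 for the list. LSM1A was lower (-0.28 ± 0.11) among 11 LSM genes in the authors' deposited table, and none of the LSM genes passed adjusted over the list alone. No gene passed among 17 SR splicing factor genes or 5 cytosolic ribosomal protein genes, and none did adjusted over the list alone. SEP3, the floral organ marker measured, was at -0.55 ± 0.28 in the authors' deposited table and passed adjusted over the list alone, a list of 1 gene. In 6x_pfd, 20 of 31 lists passed at preset correlations of 0.01 and 0.05 and 15 at 0.1.

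**Figure D2:**
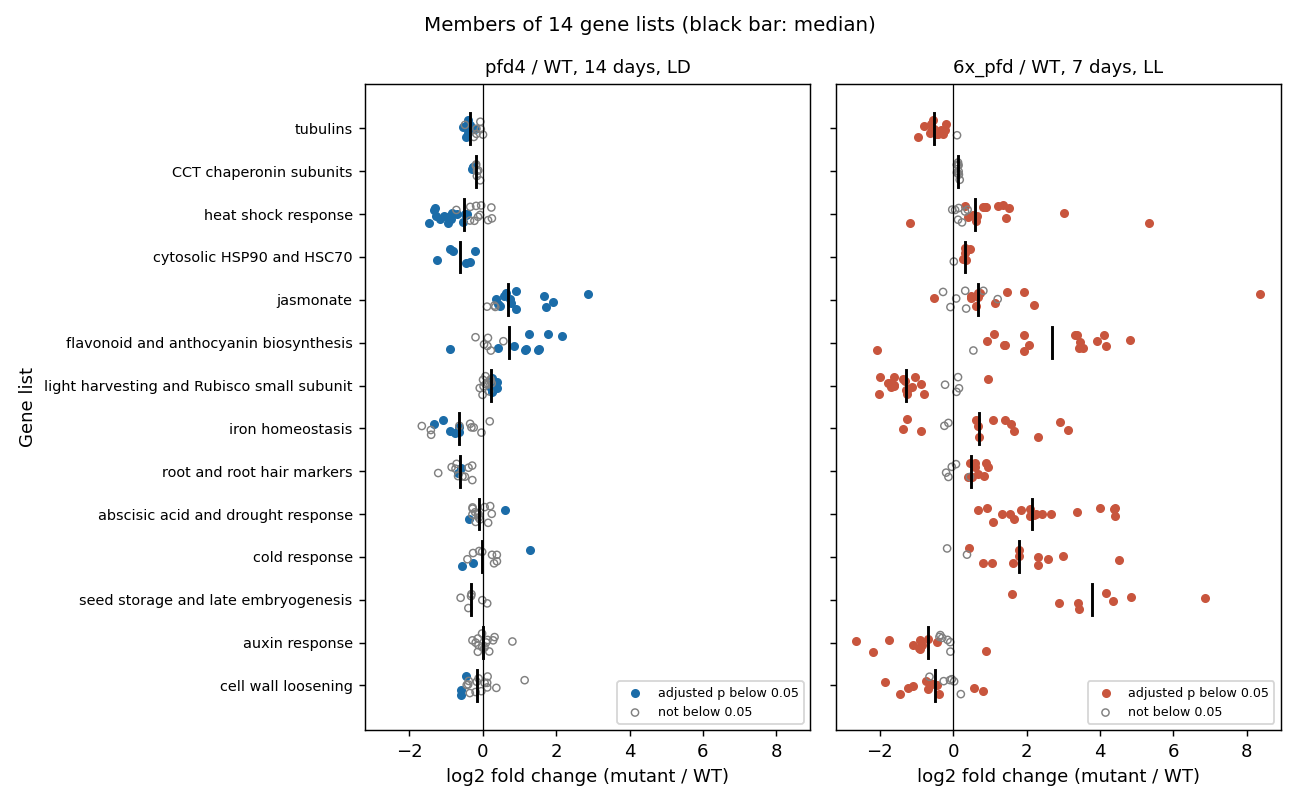
Log2 fold change (mutant over WT, horizontal axis) of each measured member of 14 gene lists (vertical axis) in pfd4 at 14 days (left) and 6x_pfd at 7 days (right), from the authors' deposited tables. Filled points have an adjusted p below 0.05, open points do not, and the black bar is the list's median, which for heat shock genes is -0.52 in pfd4 and 0.59 in 6x_pfd and for tubulins -0.33 and -0.51.

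Jasmonate and flavonoid genes rose in both mutants, while the heat shock, iron and light-harvesting lists moved in opposite directions, though not with every gene. The flavonoid genes that rose differed in part. F3H (0.13 ± 0.14) and FLS1 (0.14 ± 0.14) did not pass in pfd4 and rose in 6x_pfd (1.94 ± 0.13 and 1.39 ± 0.12) in the authors' deposited tables. Of 18035 genes tested in both, 731 passed in both of the authors' deposited tables, 274 in the same direction and 457 in opposite directions. MBP1 (4.21 ± 0.21 in pfd4 and 3.14 ± 0.16 in 6x_pfd), the TRAF-like gene AT3G28220 (2.54 ± 0.16 and 2.19 ± 0.12), AOC2 and AT1G52000 (1.83 ± 0.16 in 6x_pfd) rose in both of the authors' deposited tables. CSLA10 (1.36 ± 0.13 and 2.48 ± 0.17), the beta-glucosidase gene BGLU18 (2.02 ± 0.13 and 1.29 ± 0.13), MYB47 (1.45 ± 0.15 and 1.86 ± 0.20), HPL1 (1.08 ± 0.13 and 1.51 ± 0.16) and AT4G21910 (1.05 ± 0.11 and 1.16 ± 0.10) also rose in both of the authors' deposited tables. PFD4 fell in both.

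By direction, 129 genes were higher in both mutants against 107 for independent lists (Fisher's exact test, adjusted p = 0.0245) and 145 were lower in both against 118 (Fisher's exact test, adjusted p = 0.00976). Genes higher in pfd4 and lower in 6x_pfd numbered 232 against 121 (Fisher's exact test, adjusted p = 3.735e-25), and the converse 225 against 105 (Fisher's exact test, adjusted p = 1.317e-30). The Fisher tests were two-sided and adjusted over the 4 combinations. All 4 exceeded the number for independent lists. The tests take genes as independent and equally likely to be called, so an excess alone does not show a shared or opposed response. With an absolute log2 fold change of at least 1 also required, 40 genes went the same way and 18 opposite ways, so the share in the same direction was 69.0% in place of 37.5%. Both-higher genes then numbered 37 against 3.11 (Fisher's exact test, p = 1.029e-29). Under an abundance filter, 97 genes were higher in both against 96.1 (Fisher's exact test, p = 0.910), and after centring on library totals 153 against 165 (Fisher's exact test, p = 0.299). Genes lower in both were 3 against 0.923 with the minimum fold change (Fisher's exact test, p = 0.0644), and those higher in pfd4 and lower in 6x_pfd 8 against 4.58 in the test against a 25% change (Fisher's exact test, p = 0.141). Across all genes tested in both, Pearson's r of the log2 fold changes was -0.00457 and Spearman's rho -0.0990; genes are not independent replicates.

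**Figure D3:**
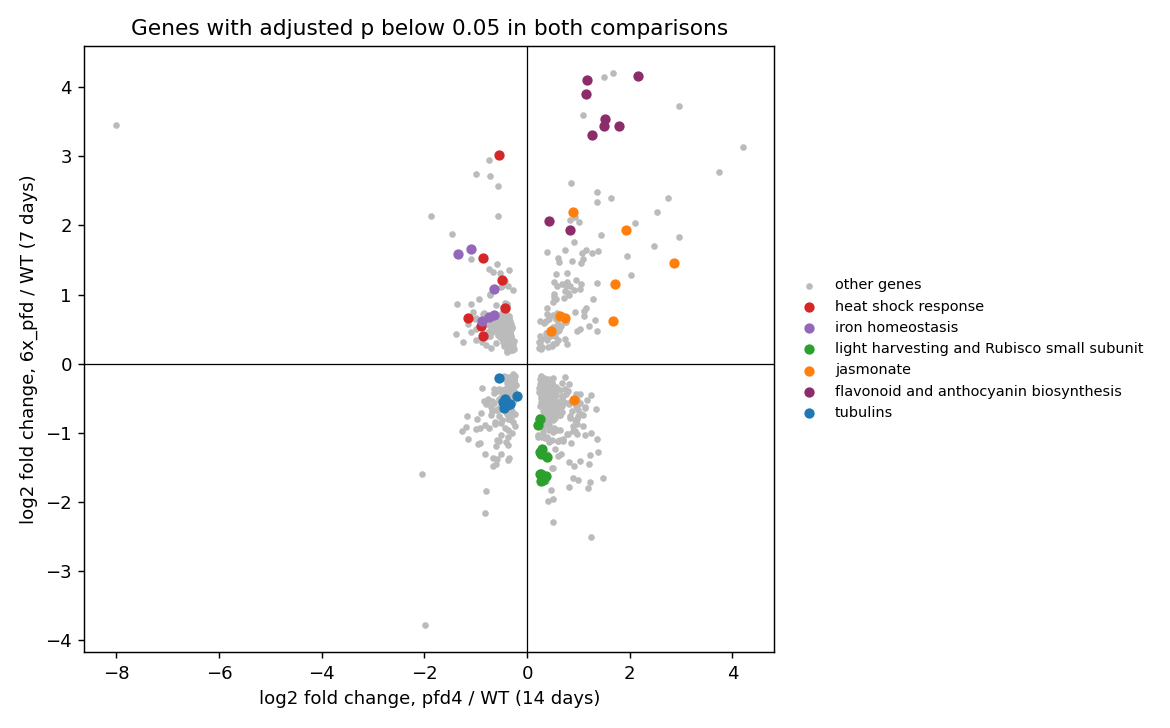
Log2 fold change (mutant over WT) in 6x_pfd at 7 days (vertical axis) against pfd4 at 14 days (horizontal axis) for the 731 genes past the threshold in both of the authors' deposited tables, each point a gene, with members of 6 lists in colour. Flavonoid genes lie at the upper right, heat shock and iron genes at the upper left, and light-harvesting genes at the lower right, within the 457 genes of opposite direction.

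The difference between the mutant effects was computed from the fold changes and SEs of both of the authors' deposited tables, and 4299 of the 18035 genes passed an FDR of 0.05, 2133 more positive in 6x_pfd and 2166 more negative. Heat shock genes differed by a median of 1.23 (6x_pfd minus pfd4, adjusted p = 2.10e-14), and 7 of 21 fell in pfd4 and rose in 6x_pfd past the threshold. HSP101 differed by 1.34 ± 0.20 and FES1A by 1.42 ± 0.20, through their fall in pfd4, since neither passed in 6x_pfd (0.05 ± 0.11 and 0.15 ± 0.12 in the authors' deposited table). The HSP90 and HSC70 genes differed by 0.94 (adjusted p = 1.805e-07) and CCT genes by 0.31 (adjusted p = 0.00132). Iron homeostasis genes differed by 1.504 (adjusted p = 9.00e-11), with IMA1 at 2.92 ± 0.25, and root markers by 1.099 (adjusted p = 8.34e-05). Light-harvesting and Rubisco small subunit genes differed by -1.53 (adjusted p = 5.98e-45), with LHCA4 at -2.00 ± 0.15. Abscisic acid genes differed by 1.98, cold genes by 1.44, flavonoid genes by 1.64 and seed storage genes by 3.81, all past the threshold at each preset correlation. Jasmonate genes did not pass as a list (median -0.01, adjusted p = 0.124). In all, 20 of 31 lists passed at a preset correlation of 0.01, 16 at 0.05 and 15 at 0.1. Those lost at 0.05 were tubulins (adjusted p = 0.0671), the clock (0.0528), salicylic acid (0.0999) and oxidative stress (0.0683), and under the abundance filter salicylic acid (0.382), oxidative stress (0.131) and chloroplast-encoded genes (0.131). Under that filter 16 lists passed, since another of the 20 kept too few members to be tested. On ranks the clock (0.0960) and oxidative stress (0.0684) lists did not pass. Genotype, age and light regime change together between the experiments and cannot be told apart in this difference.

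Near-identical paralogs, such as TUA3 and TUA5, TUB2 and TUB3, the LHCB1 and Rubisco small subunit genes, HSP90.2 to HSP90.4, AOC1 and AOC2, and AT2G04050 and AT2G04070, are uncertain as single genes, since how shared reads were counted is not given in the sources used here. The same holds for genes that overlap on opposite strands.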

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

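All tests in this part were chosen after the results were seen, except the test of photosystem subunits, and the difference between the mutant effects replaced a planned interaction.

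Of the genes past the threshold in both mutants, 457 changed in opposite directions. The difference between the effects passed an FDR of 0.05 for each of them, which follows from selecting genes with opposite effects past the threshold and adds no support. Heat shock genes were lower in pfd4 and higher in 6x_pfd, with a median difference of 1.23 (6x_pfd minus pfd4). Their levels differed between the experiments as well. Mean normalized counts over mutant and WT were 3477 at 14 days and 491 at 7 days for HSP101, and 38370 and 3623 for HSP70-4. Those of HSP70-5 went the other way, 145 and 292. HSP70-4 thus fell in pfd4 from a higher level than that from which it rose in 6x_pfd. Iron homeostasis genes differed by 1.504 and root markers by 1.099, both lower in pfd4 and higher in 6x_pfd. Genes for light-harvesting proteins and the Rubisco small subunit differed by -1.53, higher in pfd4 and lower in 6x_pfd. Genotype, age and light regime differ together between the experiments, so none of these differences can be assigned to the prefoldin genes lost.

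The lower light-harvesting transcripts of 6x_pfd, with a median of -1.33 over 18 genes, were weighed further. A smaller share of green tissue as the whole cause is argued against by the 4 Rubisco small subunit genes, with a median of 0.11, values that were known before this test was chosen. As a partial cause it stays open and may contribute: the median of 23 nuclear photosystem genes was -0.84 (bootstrap interval over genes -1.04 to -0.65). That met the bound of -0.67, given by a rule set beforehand for this explanation, although the interval includes the bound. The rule takes the bound from the light-harvesting median of the same data, and the bootstrap treats genes as independent, which they are not. Photosystem genes could fall under the other explanations weighed here too, so the result does not set this one apart. A larger share of root stays open as well. The 9 measured markers of the root and root hair list outside the CASP genes rose (median 0.60). They include root hair genes such as PRP3 and RSL4, so they need not reflect root as a whole. The 5 endodermal CASP genes, singled out after their values were seen, had a median of -0.0386. The root iron uptake genes FRO2 (-1.37 ± 0.23) and IRT1 (-1.26 ± 0.25) fell in the authors' deposited table. A difference in clock phase stays open too, as morning clock genes lay below evening ones by a median difference of -0.998 (8 of 9 morning genes lower, 4 of 8 evening genes higher), and so does an effect of prefoldin loss itself.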

How the results depend on the processing

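The FDR of 0.01 and the minimum log2 fold change were set before the data were examined, and all other alternatives were chosen after seeing the data. No paired analysis was possible because the tables analysed hold no values per library. For the same reason refits with TMM, RLE or library-size scaling, the comparison of count tools, the filters on counts, the RPKM pseudocount and filter, the list tests with an estimated correlation, the leaving out of each library and other splits of the samples were not run. No named gene or list past the threshold changed sign under the alternatives run, but the balance of directions among genes called in both mutants did, as given here. Counts fell where the threshold was stricter by construction. In pfd4, 835 genes passed an FDR of 0.01 (469 higher, 366 lower), 198 with an absolute log2 fold change of at least 1 (147 and 51), 347 with the empirical null (230 and 117) and 165 in the test against a 25% change (128 and 37). In 6x_pfd the counts were 1186 (734 and 452) with the minimum fold change, 923 (513 and 410) with the empirical null and 1779 (979 and 800) against a 25% change. Genes past the threshold in both mutants numbered 358 at an FDR of 0.01 (141 in the same direction, 217 opposite), 58 with the minimum fold change (40 and 18), 64 with the empirical null (40 and 24) and 52 against a 25% change (37 and 15). The difference between the mutants was past the threshold for 1071 genes with a minimum difference of 1, 465 with the empirical null and 1113 against a 25% change. Opposite directions outnumbered the same direction at both FDR thresholds and the reverse held under the other 3 of these settings. Genes higher in both were 129 against 107 for independent lists as deposited and 153 against 165 after centring, and 97 against 96.1 under the abundance filter. Those lower in both lost their call with the minimum fold change (3 against 0.923), and those higher in pfd4 and lower in 6x_pfd against a 25% change (8 against 4.58). The cause was not tested. Of 291 values of named genes, 86 lost their call with the minimum fold change, 74 with the empirical null, 63 against a 25% change, 13 at an FDR of 0.01 and 4 with centring on library totals, which gained 6. Under the abundance filter 237 kept their status, 2 gained a call and the rest could not be tested. Of the list results, 6 lost their call at a preset correlation of 0.05, 12 at 0.1, 6 on ranks (2 gained one), 6 under the abundance filter (1 more could not be tested) and 1 with centring (1 gained one). In the simulation with 200 changed genes per comparison, changes of 0.5 on the log2 scale were called in 53.6% of cases for pfd4 and 60.8% for 6x_pfd. With so few changed genes the adjustment is stricter than with the 1423 and 6519 genes called in the authors' deposited tables. These shares therefore do not measure how often such a change was called there.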

Other observations

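All tests in this part were chosen after the results were seen, except the count of mitochondrial stress genes; the counts of changed neighbours of the prefoldin loci were planned, but the bounds for reading them were set afterwards.

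Process terms were tested among genes past an FDR of 0.05 with an absolute log2 fold change above 1, and 12 of 972 tests passed. In 6x_pfd the lower genes held 18 of 65 photosynthesis genes against 1.399 for a random draw (Fisher's exact test, adjusted p = 1.079e-12), 7 of 17 red light response genes and 11 of 87 cell redox homeostasis genes. The higher genes held 19 of 73 abscisic acid response genes (Fisher's exact test, adjusted p = 1.253e-09), 14 of 71 water deprivation genes, 6 of 20 plant-type cell wall organization genes against 0.682 and 4 of 11 starch catabolic genes. In pfd4 the lower genes held 4 of 53 heat response genes (Fisher's exact test, adjusted p = 0.00157) and 2 of 13 hydrogen peroxide response genes (adjusted p = 0.0462). Genes annotated to the cytosolic ribosome were near 0 in pfd4 (3 of 226 higher, 4 lower, median 0.01) and 56 of 227 were higher and 10 lower in 6x_pfd (median 0.13), in the authors' deposited tables, with no list test run.

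UPOX and AOX1A, markers of the signal from stressed mitochondria to the nucleus, rose in 6x_pfd. A list of 11 further genes of that class was then written before their values were seen, and 9 of the 10 measured rose in 6x_pfd. BCS1 was at 2.33 ± 0.18, CRF6 at 1.21 ± 0.11, NAC13 at 1.02 ± 0.10 and CYP81D8 at 1.17 ± 0.19 in the authors' deposited table, and AT5G14730 at -0.55 ± 0.29 did not pass. These 9 genes are consistent with a mitochondrial stress response in 6x_pfd, which is a hypothesis, and 2 of 9 measured members rose in pfd4.

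The 6x_pfd table gives no p-value for 17 genes, with a median SE of 1.44 there. They include rapidly induced genes such as ERF6, ERF104, ZAT10 and WRKY40. The reason is not given in the sources used here, and the pfd4 table lacks a p-value for 3 genes. Such SEs leave open that single libraries of the 6x_pfd comparison differed, which needs values per library to test. WRKY33 (SE 1.12) and LOX4 (SE 1.15) of the immunity and jasmonate lists were also imprecise in 6x_pfd. The median SEs of these lists there were 0.246 and 0.180. The 17 genes all lay above 0 in pfd4, with a median of 1.34. In pfd4, 14 of them were called higher, against 0.670 for a random draw. A burst in single 14-day libraries as the whole cause is argued against by the median SE of the 17 genes, 0.257 in the pfd4 table beside that median of 1.34. Their SEs were still 1.53 times those of genes of like abundance there (13.6 times in the 6x_pfd table). Some extra spread between 14-day libraries therefore stays open, and the bound for reading this ratio was set after the data were seen. A difference in handling between all WT and all pfd4 libraries, if there was one, may explain that all 17 were higher. It cannot be told apart from genotype, since it would divide the libraries in the same way.

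AT3G01345, AT5G15360 and MRD1 (AT1G53480) were nearly absent from pfd4. Loss of PFD4 in either growth condition is argued against for MRD1 by 6x_pfd, in which PFD4 was low too and MRD1 near 0 (-0.15 ± 0.09 in the authors' deposited table), but stays open for AT5G15360, not analysed in 6x_pfd, and for AT3G01345, which was higher there (3.45 ± 0.48) but had too few counts in 7-day WT for a fall to be seen, about 5.57 normalized counts against 3900 in 14-day WT as implied by the means and fold changes of the authors' deposited tables. A changed chromosome segment that shifts its neighbours by at least 1 on the log2 scale is argued against for AT3G01345 and AT5G15360. Beside them 0 of 20 genes changed that much, and 1 of 10 passed the threshold at each locus. A segment that left neighbouring transcripts little changed could not be seen in this way and stays open. For MRD1 a changed segment stays open too. There 1 of 10 neighbours changed by at least 1, the adjacent HEI10 (AT1G53490, -1.13 ± 0.27 in the authors' deposited table), and 3 of 10 passed the threshold. A sequence or chromatin difference at single genes between seed stocks could account for all 3 and stays open, as 96.7% of the 30 neighbours were not changed to that degree and no genome data were analysed here. An effect of PFD4 loss under the 14-day condition alone was not tested.

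Among the 20 genes around PFD4, 3 changed in pfd4 (permutation p = 0.205 over 10000 random windows, 0.491 adjusted over single loci in both comparisons), and around all 6 prefoldin loci 42 of 120 genes changed in 6x_pfd against a random median of 40 (permutation p = 0.412).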
